A study of Mus musculus with 12 samples.

How the data were processed

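Gene expression was measured by RNA sequencing in 12 samples of mouse cortical neuronal cultures, 6 labelled IFNG and 6 labelled Control. Per the labels' protocols, cultures were transduced at 7 days in vitro with a lentivirus that overexpresses Ifng, the gene of interferon-gamma, and were harvested 10 days later, and libraries were made by poly(A) enrichment. All samples carry that same protocol text, so the labels do not say which construct, if any, the Control cultures received.

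The authors deposited a table of raw counts per gene, whole numbers that were not normalized, with 43629 Ensembl gene identifiers and a column for each sample. Per the submitters' processing notes, the tools were STAR 2.4 and DESeq2, and the genome builds named were GRCm39 and mm10, with no role given for any of them. The read counter, its strand setting and the gene annotation are not given in the sources used here. Reads from stretches where neighbouring genes overlap on opposite strands, and reads of near-identical genes such as the Tgtp, Gbp, H2, Oas and Irg families, are therefore uncertain as to which gene they came from. Gene symbols and coordinates were taken from the GENCODE M21 annotation of build GRCm38, which matched 42462 identifiers and may not be the annotation used to count. The listed genes Gbp5, Gbp6 and Gbp10 had no row under those symbols. Identifiers without a symbol held between 0.133 and 0.158% of the counts of a library and stayed in the tests.

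Library totals ran from 13875435 to 34239380 counts. A chi-square comparison of each pair of libraries within a group gave at least 7.40 per gene, so no pair agreed within sampling noise and all 12 were used as separate samples. The labels do not say whether the samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Intervals on counts are exact 95% intervals (a confidence level of 0.95) and cover counting error only. The floor was 3 counts over the group. For a gene at 0 in all controls, the fold is given as a lower bound against that floor. For a gene with 1 to 3 control counts, the ratio of counts is given with its interval.

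The comparison was IFNG against Control in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter on low counts, quasi-likelihood F-tests (two-sided) and Benjamini-Hochberg adjustment at 0.05, with no block. This left 15241 genes. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library totals. The scores of gene lists are means of log2 CPM over their tested members, with a prior count of 2.

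There were 38 gene lists, holding 828 different genes. They were fixed before the data were examined, as were the main test, all but 2 of the alternatives and the rule for the genes named. Lists with at least 3 tested genes (36 of 38) were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list. The self-contained test fry was also run. Adjusted p-values of lists are Benjamini-Hochberg values over the 36 lists. Members that passed were counted among all genes tested and also adjusted over the list alone. The rule for named genes took Ifng, its receptor genes, the immunoproteasome genes with their constitutive counterparts, and Pfkfb3. It added the 10 genes with the largest rise and the 10 with the largest fall among those past the test with a mean log2 CPM of at least 3, groups that did not overlap and a proper gene symbol. From each list it took up to 3 members with the smallest p and the most abundant member that did not pass. Other genes are named where 5 or fewer of a list changed, or as examples, and were chosen after their values were seen. Results of some genes of the lists and of the naming rule are not reported here; they remain in the tests and in the counts of lists and comparisons, and were left out of the check for libraries that stand apart.

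On counts simulated from the Control means and the real library sizes, with 14723 genes tested, the test recovered 56% of 100 genes changed 1.5-fold and 81% of 100 genes changed 2-fold. The changed genes were not near 0 in Control, and rises and falls were equal in number. Far fewer genes changed than in the real comparison, so the simulation does not cover a shift in composition. It made 143 calls, of which 6 were false, and called 0 of 20 unchanged lists. Simulated genes vary independently, so this last figure does not cover lists whose genes vary together between cultures.

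Alternatives were DESeq2 size factors in the same fit, library totals without a composition factor, no filter, a filter of at least 1 CPM in 6 samples, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, and a test against a fold change of 1.2. For the lists there were also the estimated correlation, fry, and lists without the genes of the 2 interferon lists. A pair of alternatives was chosen after seeing the data, namely leaving out IFNG 3 and IFNG 5, and library totals that leave out every gene that rose. Figures were drawn with matplotlib 3.10.9.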

Results

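The data were counts of poly(A) RNA per gene in 12 libraries of mouse cortical neuronal cultures, 6 labelled IFNG and 6 labelled Control. By the series' description, the IFNG cultures were under lasting interferon-gamma exposure from a lentiviral Ifng construct, added at 7 days in vitro, and were harvested 10 days later. Control libraries held 17754401 ± 1920310 counts and IFNG libraries 21036991 ± 7516016 counts (SD, n = 6 each). Mitochondrially encoded genes took 4.58 ± 1.0% of the counts in Control and 4.77 ± 0.71% in IFNG libraries (SD, n = 6 each). The series asks what lasting exposure to interferon-gamma does to neurons, and its title concerns immunoproteasomes and neuronal metabolism. Both questions are read here from the comparison of IFNG with Control. Log2 fold changes are given with their standard error (SE), and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15241 genes.

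Ifng (ENSMUSG00000055170, GRCm38 chromosome 10, 118441046 to 118445892, plus strand) was read at 11.1 ± 4.41 CPM in IFNG libraries and 0.069 ± 0.078 CPM in Control libraries (SD, n = 6 each). Its log2 fold change was 7.27 ± 0.48 (adjusted p = 3.45e-10). The IFNG libraries ranged from 4.98 to 17.9 CPM, and no Control library held more than 3 Ifng counts. An exact two-sided permutation test over the 924 arrangements of the labels gave p = 0.00216, the smallest it can give. The receptor gene Ifngr1 rose by 0.86 ± 0.17 (adjusted p = 0.00069), and Ifngr2 had a log2 fold change of -0.24 ± 0.12 (adjusted p = 0.160). The labels of all 12 libraries matched their Ifng level.

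Of the 15241 genes tested, 2184 were higher and 1492 lower in IFNG than in Control, together 24.1%. The rises were the larger changes: 1020 genes were higher by 2-fold or more and 288 by 8-fold or more, against 119 lower by 2-fold or more. The higher calls made up 59.4% of all calls. On library totals without a composition factor 1962 genes were higher and 1859 lower, or 51.35% higher. On library totals that leave out the genes that rose, an alternative chosen after seeing the data, 2961 genes were higher and 752 lower, or 79.7% higher. That scaling moved the median log2 fold change of all genes from -0.02 to 0.10, and it pushes all genes up by construction, since the risen genes took 9.27% of Control counts and 18.4% of IFNG counts. Tested against a fold change of 1.2, 1493 genes were higher and 458 lower.

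Nearly all listed genes of the interferon response rose. In the list of interferon-gamma response genes, 27 of 28 tested members rose and none fell, with a median log2 fold change of 8.42, or 7.84 with genes absent from Control set at their lower bound. The transcription factor Irf1 went from 3.40 ± 0.57 to 213 ± 19.9 CPM (SD, n = 6 each), and Irf8 from 0.838 ± 0.266 to 133 ± 14.9 CPM. The guanylate-binding protein gene Gbp7 rose by 7.37 ± 0.15 on the log2 scale (adjusted p = 1.35e-17). Jak1, a kinase of the receptor, was the member that did not pass, at 0.19 ± 0.093 (adjusted p = 0.161). Of the 32 genes commonly used as a type I interferon signature, 31 rose, with a median of 7.21. Trim30a rose by 8.92 ± 0.29 and Bst2, which holds budding virus at the cell surface, by 8.89 ± 0.29. The antiviral gene Oas3 lay near the detection limit, at 0.528 ± 0.471 CPM in Control and 0.880 ± 0.587 CPM in IFNG libraries (adjusted p = 0.439). Both lists passed camera with the preset correlation and with an estimated correlation (adjusted p = 1.78e-05 and 0.00050), and their counts were the same adjusted over the list alone.

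The 10 genes with the largest rise under the naming rule were H2-Aa, H2-Eb2, Gbp8, Ifi44, H2-Ab1, Ifi47, Tgtp1, Tgtp2, Sp100 and Serping1. H2-Aa (chromosome 17, 34282744 to 34287823, minus strand) went from 0.0497 ± 0.0501 to 388 ± 106 CPM (SD, n = 6 each). H2-Eb2 had 0 counts in all Control libraries and 4042 in the IFNG libraries, at least 1137-fold higher. Sp100, a nuclear body gene, had 1 count in Control, and its ratio of counts was 2032, with an exact 95% interval of 364.4 to 80290. Log2 fold changes of the other 7 lay between 10.21 for Serping1 and 11.74 for Gbp8. Tgtp1 and Tgtp2 are near-identical copies, so how their reads were divided is uncertain.

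Proteasome genes split by kind. The immunoproteasome replaces the catalytic subunits of the standard proteasome in immune settings, and all 5 genes of its list rose. Psmb8 rose by 8.32 ± 0.28 and Psmb9 by 8.16 ± 0.24, from 0.342 ± 0.270 and 0.476 ± 0.235 CPM to 111 ± 22.8 and 139 ± 36.2 CPM (SD, n = 6 each). Psmb8 (34197721 to 34201454, plus strand) and Psmb9 (34181987 to 34187764, minus strand) lie beside Tap1 on chromosome 17 in GRCm38, where Tap1 spans 34187553 to 34197225 on the plus strand. Psmb9 and Tap1 overlap there only at their starts, on opposite strands, and without the strand setting the reads of that short stretch are uncertain. Psmb10, on chromosome 8, rose by 3.24 ± 0.14. The activator subunits Psme1 and Psme2 rose by 2.31 ± 0.11 and 2.43 ± 0.13. The constitutive counterparts Psmb5, Psmb6 and Psmb7 did not pass, at 0.27 ± 0.12, 0.17 ± 0.10 and 0.21 ± 0.095 (adjusted p = 0.110, 0.234 and 0.116). On totals without the genes that rose, Psmb5 and Psmb7 passed, at 0.38 and 0.33. Of 36 other core, regulatory and assembly genes, 14 rose and none fell, or 15 adjusted over the list alone, all by less than 2-fold. Psmb2 rose by 0.61 ± 0.10 and the assembly chaperone Pomp by 0.49 ± 0.11. That list did not pass camera (adjusted p = 0.0759), but it did without Control 4, IFNG 4 or IFNG 6 (0.0189, 0.0409 and 0.0298). It also passed with no filter on low counts (0.00835), on totals without the genes that rose (0.0278) and with fry (0.0110). Control 4 stood apart in its mean log2 CPM, at 6.33 against 6.11 to 6.15 in the other Control libraries. The immunoproteasome list passed with an estimated correlation (adjusted p = 0.00022).

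**Figure D1:**
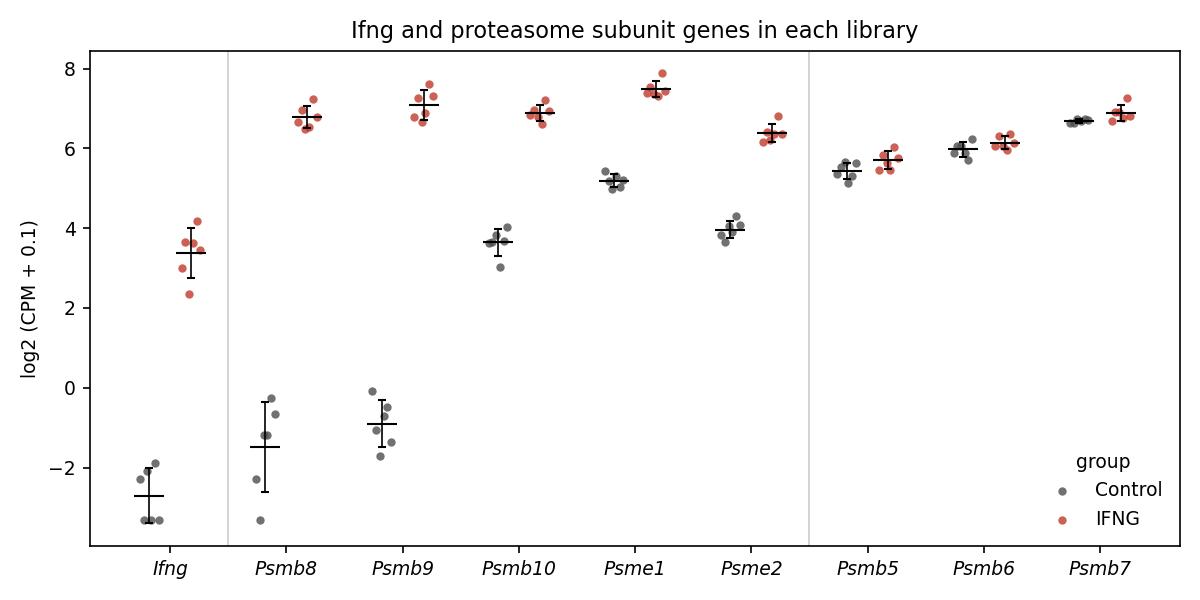
Levels of Ifng, the 5 immunoproteasome genes and the 3 constitutive catalytic subunit genes in each library, as log2 of CPM plus a pseudocount of 0.1, with 6 Control (grey) and 6 IFNG (red) points per gene; horizontal lines are group means and error bars are SDs. The groups are apart for Ifng, Psmb8, Psmb9, Psmb10, Psme1 and Psme2 and overlap for Psmb5, Psmb6 and Psmb7, which did not pass the test.

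Antigen presentation genes rose with them. In the list of class I presentation, 15 of 16 genes rose, with a median log2 fold change of 6.17. The peptide transporter gene Tap1 went from 6.83 ± 0.76 to 618 ± 140 CPM and H2-K1, a class I heavy chain, from 8.31 ± 2.01 to 1366 ± 386 CPM (SD, n = 6 each). H2-T24 had a log2 fold change of 0.28 ± 0.30 (adjusted p = 0.557). In the class II list all 8 tested genes rose, of 14 fixed, with a median of 8.53. They included Ciita, the master regulator of class II genes, at 6.85 ± 0.24, and H2-Ab1 at 11.41 ± 0.39. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 together reached 2604 ± 862 CPM in IFNG against 2.29 ± 1.39 CPM in Control libraries (SD, n = 6 each). The summed level of 10 abundant microglial genes stood at 2.99 ± 1.06 CPM in IFNG and 2.81 ± 0.86 CPM in Control libraries. Single genes of that sum moved both ways: from Control to IFNG, C1qa went from 3 to 57 counts and Cx3cr1 from 22 to 10. Both lists passed with an estimated correlation (adjusted p = 0.00010 and 0.00022), and their counts were the same adjusted over the list alone. Reads of H2 genes may be shared between family members.

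Secreted and surface mediators of inflammation rose in most lists. Of 14 tested chemokine and cytokine genes 12 rose, among them Cxcl10, which attracts T cells, at 7.15 ± 0.38, and the death ligand Tnfsf10 at 9.99 ± 0.27. Cx3cl1, a chemokine abundant in neurons, stood at 587 ± 45.1 and 610 ± 28.5 CPM (SD, n = 6 each; adjusted p = 0.661). Of 8 tested complement genes 7 rose, including C1s1 at 7.04 ± 0.22 and C1ra at 7.55 ± 0.33, and Cd55 had a log2 fold change of -0.33 ± 0.29 (adjusted p = 0.454). Of 15 NF-kB target genes 11 rose, or 13 adjusted over the list alone, with the adhesion molecule genes Icam1 at 6.96 ± 0.24 and Vcam1 at 3.73 ± 0.15. Sod2, a target in the same list, stood at -0.13 ± 0.087 (adjusted p = 0.292). All 3 lists passed with an estimated correlation (adjusted p = 0.00022, 0.00122 and 0.0115). In the list of ubiquitin conjugation and the ubiquitin-like ISG15, 11 of 18 genes rose and 1 fell, or 11 and 2 adjusted over the list alone. Those that rose included Uba7, the enzyme that activates ISG15, at 7.08 ± 0.24 and Herc6 at 5.62 ± 0.19, while Fbxw7 fell by 0.44 on the log2 scale. The abundant ubiquitin gene Ubb stood at 0.07 ± 0.083 (adjusted p = 0.626). This list passed with an estimated correlation (adjusted p = 0.00050).

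Among cell death genes and p53 targets 11 of 26 rose and 2 fell, or 13 and 4 adjusted over the list alone. The inflammatory caspase gene Casp1 rose by 6.10 ± 0.29 and Casp12 by 6.45 ± 0.31. Mlkl, which executes necroptosis, had 3 Control counts and a ratio of counts of 483.5, with an exact 95% interval of 165.2 to 2347. Pmaip1, which promotes apoptosis, was among those that fell, by 1.14 on the log2 scale. Mcl1, an inhibitor of apoptosis, stood at 0.02 ± 0.091 (adjusted p = 0.914). The list passed with an estimated correlation (adjusted p = 0.00157). Of 16 targets of the oxidative stress regulator NRF2, 10 rose and none fell, or 11 adjusted over the list alone. Their median log2 fold change was 0.52, in libraries where all 18 tested astrocyte markers also rose, by a median of 1.42. The gene of NRF2 itself, Nfe2l2, rose by 1.47 ± 0.13, and Gclc, of glutathione synthesis, by 0.81 ± 0.084. Srxn1 stood at 0.24 ± 0.15 (adjusted p = 0.269). This list passed camera with the preset correlation and not with an estimated one (adjusted p = 0.268 with an estimated correlation).

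Some genes of energy metabolism rose, most of them by less than 2-fold, in libraries where all 18 tested astrocyte markers also rose, by a median log2 fold change of 1.42. Pfkfb3, whose enzyme makes an activator of glycolysis, went from 59.6 ± 5.65 to 95.4 ± 6.03 CPM (SD, n = 6 each; log2 fold change 0.68 ± 0.087, adjusted p = 5.60e-06). In the glycolysis list 10 of 28 genes rose and 1 fell, or 11 and 1 adjusted over the list alone. Aldoc, which is also in the astrocyte list, rose by 1.73 and Pdk1 fell by 0.43 on the log2 scale. The list did not pass camera (adjusted p = 0.286) but passed fry, which does not compare a list with other genes (adjusted p = 0.0016). In the pentose phosphate pathway 4 of 8 genes rose (G6pdx, Pgd, Tkt and H6pd, by 0.28 to 0.58). The list did not pass camera (adjusted p = 0.286) but passed fry (adjusted p = 0.0025). Of 74 nuclear genes of the respiratory chain 10 rose, or 1 adjusted over the list alone (camera adjusted p = 0.0697). IFNG 5 stood apart in the mean log2 CPM of this list, at 6.61 against 6.03 to 6.19 in the other IFNG libraries, and without it 6 genes rose (camera adjusted p = 0.313). The list passed without IFNG 1, IFNG 4, IFNG 6, Control 4 or Control 6 (0.02497 to 0.04218). It also passed with no filter on low counts (0.00255) and on totals without the genes that rose (0.0298). Of 17 genes of the tricarboxylic acid cycle 2 rose, among them Suclg2 by 0.57 (camera adjusted p = 0.974). None of 22 cholesterol synthesis genes passed in edgeR (camera adjusted p = 0.0845). Their list passed without Control 2 or IFNG 3 (0.0462 and 0.00727), without IFNG 3 and IFNG 5 together (0.0213) and with no filter on low counts (0.0472). None of the 13 mitochondrially encoded or 74 ribosomal protein genes passed (camera adjusted p = 0.571 and 0.974).

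Markers of astrocytes, the supporting glia that neuronal cultures can contain, rose throughout. All 18 tested markers were higher in IFNG, with a median log2 fold change of 1.42 and the same count adjusted over the list alone. Aldh1l1 went from 69.0 ± 10.2 to 203 ± 19.4 CPM, and the glutamate transporter gene Slc1a3 from 774 ± 62.3 to 2429 ± 469 CPM (SD, n = 6 each). Vim rose by 1.77 ± 0.13, Ntsr2 by 0.39 ± 0.13. The list passed with an estimated correlation (adjusted p = 0.0184). Of 20 microglial and macrophage markers only 5 had enough counts to be tested; P2ry12 and Sall1 rose, or 3 adjusted over the list alone, and P2ry12 reached 0.965 ± 0.420 CPM (SD, n = 6). In the oligodendrocyte lineage Cnp rose by 2.13 while Pdgfra fell by 0.65 and Olig2 by 0.35, of 11 tested. Of 3 tested endothelial markers Ly6c1 rose, from 1 count over the Control libraries. Among 10 tested fibroblast and mural markers Igf2, Pdgfrb, Fn1 and Fbln1 rose. Of 17 markers of dividing cells Pcna and Mki67 fell, by 0.34 and 0.61, or 1 gene adjusted over the list alone. None of these 5 lists passed camera (adjusted p = 0.286, 0.977, 0.209, 0.236 and 0.161). With no filter on low counts the fibroblast and mural list passed camera (0.0486). With fry, which does not compare a list with other genes, the microglial, endothelial, and fibroblast and mural lists passed as higher (adjusted p = 0.00027, 0.00026 and 1.87e-06). The oligodendrocyte lineage and dividing cell lists did not pass fry (adjusted p = 0.235 and 0.121). Only 1 of 14 lymphocyte markers and 2 of 10 tryptophan and itaconate genes had enough counts to be tested; of these Ido2 rose by 1.07 ± 0.37.

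Neuronal genes moved less, and mostly down, beside this rise of astrocyte markers. Of 114 tested genes in the 5 neuronal lists 44 fell, with a median log2 fold change of -0.27 over all 114. Among genes of glutamatergic neurons and excitatory synapses 10 of 25 fell and Nptx1 rose, or 11 and 2 adjusted over the list alone. Control 4 stood apart in the mean log2 CPM of this list, at 7.51 against 7.68 to 7.79 in the other Control libraries. Without Control 4, 12 of the genes fell. Nrgn, of the postsynapse, went from 216 ± 32.8 to 102 ± 31.7 CPM (SD, n = 6 each). Nptxr stood at -0.20 ± 0.074 (adjusted p = 0.0582). Of 21 genes of GABAergic neurons 6 fell and Sst, of an interneuron class, rose, by 0.77 ± 0.11, while Calb2 fell by 1.30 and Dlx1 by 0.99. Of 23 presynaptic genes 9 fell, or 12 adjusted over the list alone, including Rab3a, Syn1 and Vamp2 by 0.46, 0.42 and 0.37, with Syt1 at -0.25 ± 0.096 (adjusted p = 0.0700). Of 24 pan-neuronal genes 13 fell, including Stmn1 by 0.55, Dcx by 0.83 and Ina by 0.42. Of 21 voltage-gated channel genes 6 fell, including Kcnd2 by 0.39, Cacnb4 by 0.55 and Cacng3 by 0.45. IFNG 5 stood apart in the mean log2 CPM of the channel list, at 5.84 against 6.35 to 6.56 in the other IFNG libraries, and without it 4 of the genes fell and the difference between group means went from -0.23 to -0.13. The calls of these 5 lists were lost with an estimated correlation (adjusted p = 0.423, 0.536, 0.268, 0.202 and 0.569). With fry, which does not compare a list with other genes, all but the channel list passed as lower (adjusted p = 0.0033, 0.032, 0.00027, 0.00013 and 0.0519). With the preset correlation, the GABAergic call was also lost without any of Control 1, Control 2, Control 3, IFNG 5 or IFNG 6 (adjusted p = 0.0505 to 0.0989), and the channel call without Control 3 or IFNG 5 (0.0633 and 0.104). On totals without the genes that rose, 27 of the 114 genes fell and their median was -0.16. Relative to the median of all genes, the median of the 114 was -0.25 on either scaling, a difference that a common shift of all genes leaves unchanged by construction.

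**Figure D2:**
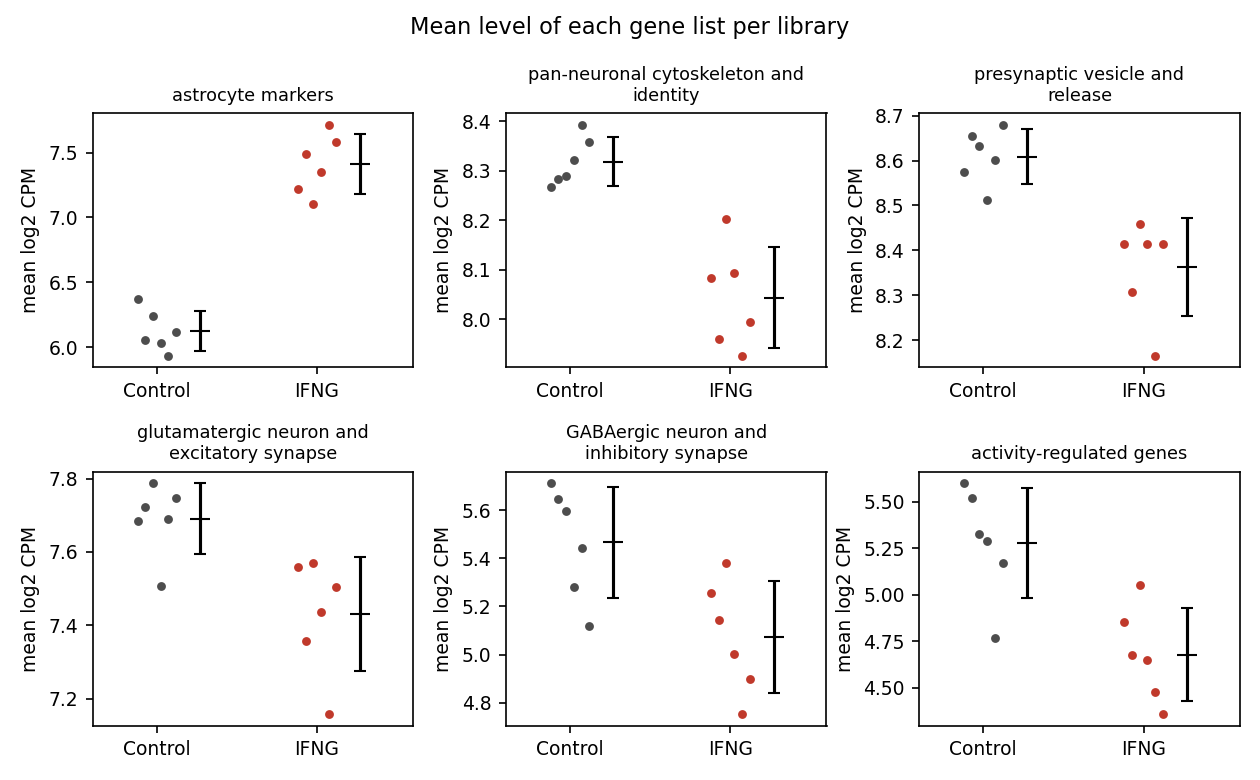
Mean log2 CPM over the tested genes of 6 lists in each library, with 6 Control (grey) and 6 IFNG (red) points; the bar beside each group is the mean and its SD, and each panel has its own vertical scale. Astrocyte markers averaged 6.13 in Control and 7.41 in IFNG libraries, pan-neuronal genes 8.32 and 8.04.

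Of 23 genes that neuronal activity induces 14 fell and Jun rose, or 15 and 1 adjusted over the list alone, with a median log2 fold change of -0.58, beside -0.30 for the pan-neuronal list and 1.42 for astrocyte markers. The transcription factor gene Fosb went from 21.9 ± 10.6 to 5.49 ± 1.76 CPM (SD, n = 6 each) and was also the gene with the largest fall under the naming rule. The secretory granule gene Scg2 fell by 0.94, while Vgf stood at 0.08 ± 0.12 (adjusted p = 0.669) and Jun rose by 0.81 ± 0.10. The call of this list was lost with an estimated correlation (adjusted p = 0.415), while it passed as lower with fry (adjusted p = 0.0044). The other genes with the largest falls were Klhl4, Cpne4, Sp9, Zbtb16, Calb2, Ypel2, Hdac9, Adarb2 and Vwc2l, of which Klhl4 fell by 1.59 and Hdac9 by 1.24 on the log2 scale.

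Stress lists other than NRF2 targets and cell death did not pass camera in the main fit. With no filter on low counts, the lists of glutathione and ferroptosis, heat shock, and autophagy and lysosome passed (adjusted p = 0.0407, 0.0472 and 0.0052). The same lists passed as higher with fry, which does not compare a list with other genes (adjusted p = 0.0013, 0.00026 and 0.0025). The list of unfolded protein and integrated stress responses did not pass fry (adjusted p = 0.197). Of 22 genes of glutathione and ferroptosis 6 rose and 3 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.135), the fallen genes being Ptgs2, Tfrc and Gss. Of 24 genes of the unfolded protein and integrated stress responses 7 rose and Trib3, Ppp1r15a and Atf6 fell (camera adjusted p = 0.762). Of 14 heat shock genes Hspb8, Bag3 and Cryab rose and Hspa1b fell (camera adjusted p = 0.209). Of 20 genes of autophagy and the lysosome 8 rose and Becn1 fell (camera adjusted p = 0.0929).

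**Figure D3:**
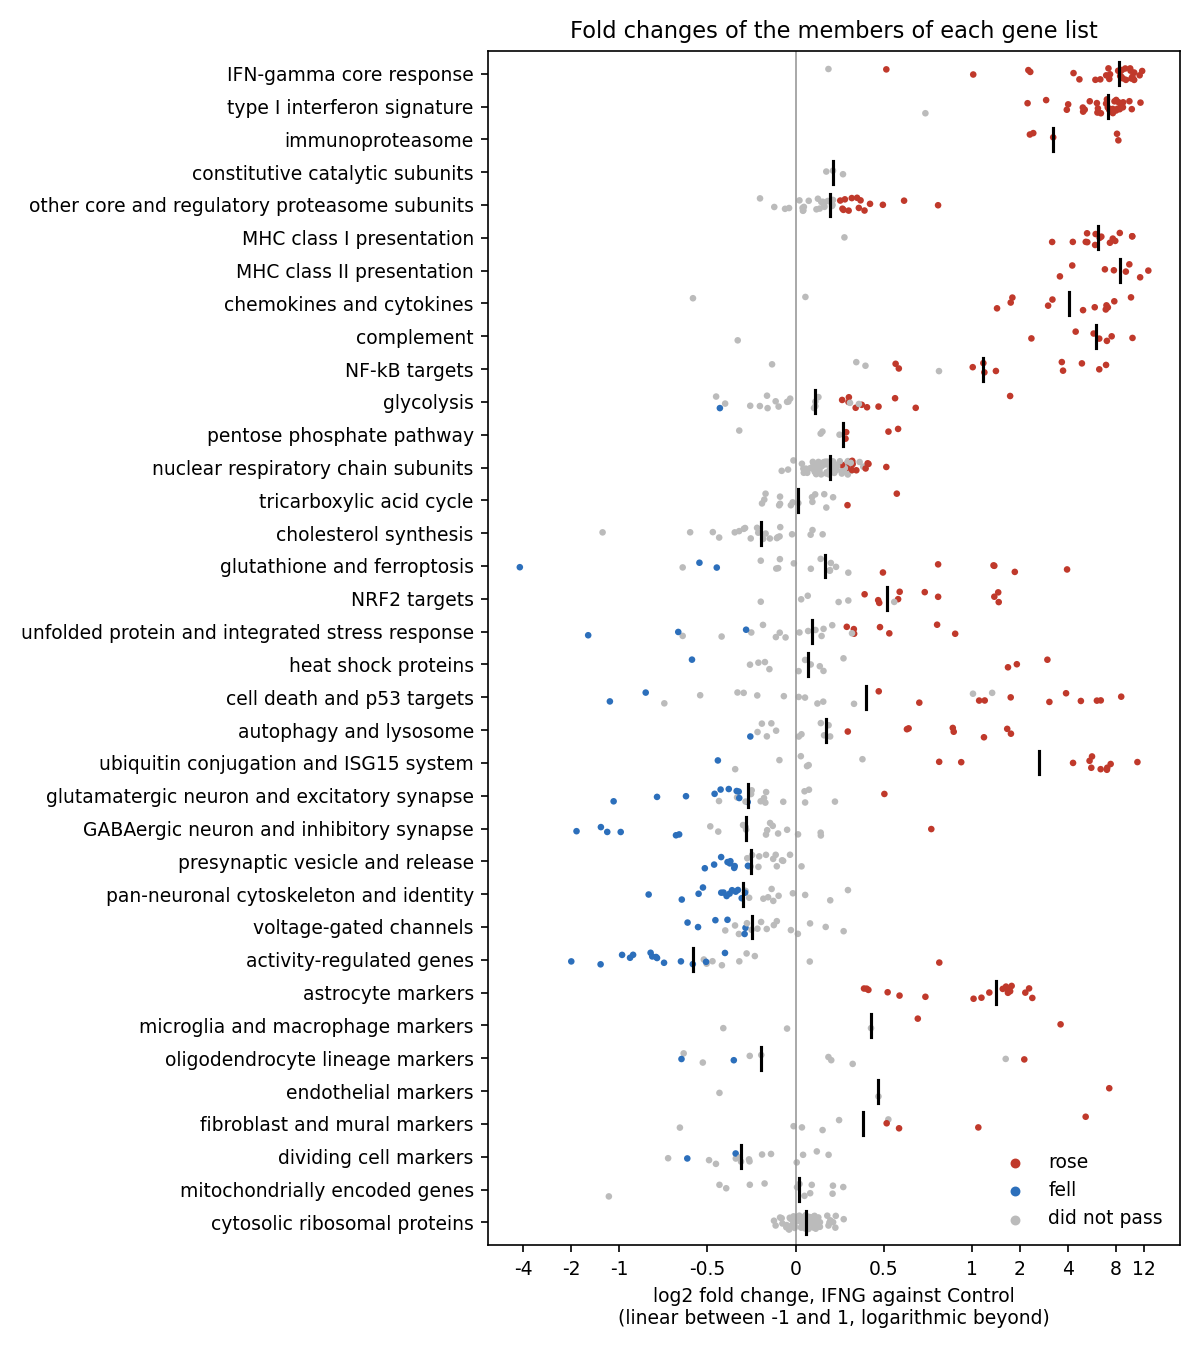
Log2 fold changes, IFNG against Control, of the tested genes in the lists with at least 3 tested members; the axis is linear between -1 and 1 and logarithmic beyond, and each point is a gene. Red points rose, blue points fell, grey points did not pass, and black bars are list medians, from 8.53 for class II presentation to -0.58 for activity-regulated genes.

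With camera's preset correlation 12 of the 36 lists tested were higher and 6 lower, and with an estimated correlation 11 were higher and none lower. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 53 gave at least 12 lists in a direction and 68 at least 6, with the preset correlation. Most of these put more of the IFNG libraries on a side and so keep part of the group difference; of the 39 with 3 IFNG libraries on each side none gave 12 lists and 7 gave at least 6. The calls of single genes do not depend on that correlation, and no other split gave over 560 genes in a direction. Every other split puts both labels in the same group, so the difference between labels widens the spread there and lowers the gene calls. The counts of genes and lists in such splits are therefore not those of unchanged libraries.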

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

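The test of oligodendrocyte against astrocyte markers, both tests of the source of class II transcripts and the division of splits by their IFNG libraries were chosen after the result was seen, while the criteria of the other tests in this part were written before their results were seen. Samples that stood apart from the other 5 of their group, by a gap past Dixon's 95% critical value, numbered 14 among 186 groups checked, and chance flags about 1 in 20.

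IFNG 5, the library with the highest Ifng level, stood apart in 9 of these measures. In list scores, which were checked separately, it also stood apart for respiratory chain, channel and ribosomal protein genes. The ribosomal protein score was 7.572 in IFNG 5, against 6.882 to 7.069 in the other IFNG libraries. Ribosomal protein genes took 1.707% of its counts (1.088 to 1.218 in the other IFNG libraries). It was highest in Psme1 at 235.7 CPM (158.3 to 184.5), Psme2 at 111.7 (70.86 to 85.18), Psmb7 at 154.2 (102.1 to 121.1), Sst at 132.9 (83.7 to 99.85) and Vgf at 827.6 (608.1 to 673.4). It was lowest in Zbtb16 at 5.113 CPM (10.39 to 12.42), Dcx at 91.31 (172 to 208.9) and Cacnb4 at 43.06 (78.35 to 96.17). In IFNG 3, which had the lowest Ifng level, the 10 most abundant genes took 4.397% of counts (5.684 to 6.449 in the others). Among Control libraries, Control 4 was highest in Tgtp2 at 1.30 CPM (0 to 0.339) and held the only Sp100 count, 0.0565 CPM. Control 5 was highest in Casp12 at 1.30 CPM (0.106 to 0.484), and Control 1 was lowest in H2-Q4 at 0.6338 (1.422 to 1.744).

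The number of genes changed exceeded what other splits of these libraries gave, but those splits are no set without change. Each puts both labels in the same group, so the difference between labels adds to the spread there and lowers the gene calls. The highest count was 0 genes in splits with 3 or with 4 IFNG libraries on the fuller side. Of 100 of the 462 distinct splits into 6 and 6, only the real split gave as many genes higher as 2184 (1 of 100) or lower as 1492 (1 of 100), and the highest of the others gave 560. Taking the larger direction of each split, 53 of 100 splits gave at least the 12 lists higher and 68 of 100 at least the 6 lists lower, with 21 the highest of the others, so these splits as a whole do not exclude chance for either count. Splits with 4 or 5 IFNG libraries on a side keep part of the group difference, however, and are no set without change. Of the 39 splits with 3 IFNG libraries on each side, the highest gave 8 lists, below the 12 higher, while 7 gave at least 6. Chance therefore stays open for the lists lower. These 39 splits also hold the difference between labels within each group, so they cannot exclude chance for the lists higher. The correlation between genes estimated within a list was above the preset 0.01 in 32 of the 36 lists.

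Astrocyte markers rose while neuronal genes fell. A larger share of astrocytes as the whole cause would raise markers that neurons hardly use by a common factor, but the log2 fold changes of such markers (0.39 to 1.68, SE 0.10 to 0.15) differed by more than their errors (chi-square test of heterogeneity, p = 2.224e-19). A smaller share of neurons alone would raise markers of every other cell type alike. Oligodendrocyte lineage markers had a median of -0.19 against 1.42 for astrocyte markers (permutation of marker labels, 100000 draws, one-sided p = 0.00068). Microglial, endothelial, and fibroblast and mural markers had medians of 0.43, 0.47 and 0.38, with 5, 3 and 10 genes tested. Their lists passed as higher with fry but not with camera in the main fit. The rises were not alike, but the permutation takes no account of genes that vary together. Whether interferon-gamma itself moved the oligodendrocyte genes was not tested, so a smaller share of neurons is not excluded. A trend with gene length or GC content does not account for the whole fall. Its median over the 44 fallen neuronal genes was -0.055, beside their median log2 fold change of -0.41. After its removal 90.91% of them stayed below 0 by more than their 95% interval, though they had been picked as fallen. Dilution by the risen transcripts does not account for the whole fall either, since without those transcripts the neuronal median was still -0.1588. On that scaling 27 neuronal genes passed as lower, against 44. It raises all genes alike, as undoing a dilution would, so the lost calls neither show nor exclude a part played by dilution. A mixture of more astrocytes with regulation inside astrocytes, and loss of neurons with lower expression in them, stays open, since bulk libraries hold no count of cells.

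Class II genes reached high levels in cultures labelled neuronal, and the cells that made them are not known. Microglia or macrophages as the only source would bring their own abundant transcripts, but 10 of these summed to at most 0.1764% of the 4 class II genes in any IFNG library. Microglial genes can themselves fall under interferon-gamma, which these libraries cannot exclude, and they stood at 2.99 ± 1.06 CPM in IFNG and 2.81 ± 0.86 CPM in Control libraries. Across the 6 IFNG libraries the score of these 4 genes followed astrocyte markers (r = 0.9815, exact permutation p = 0.00139; rho = 1, p = 0.00278) and ran against neuronal genes (r = -0.9451, p = 0.00278; rho = -0.9429, p = 0.0167), the opposite of what was set down for neurons as the source. Neurons and astrocytes cannot be told apart as the source by these values, because Ifng itself followed the class II score (r = 0.9367, p = 0.0125; rho = 0.8286, p = 0.0583) and ran against the neuronal score (r = -0.8802, p = 0.0264; rho = -0.9429, p = 0.0167), and a higher dose that induces class II in any cell and lowers neuronal genes would give the same relations.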

How the results depend on the processing

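Leaving out IFNG 3 and IFNG 5, and scaling by library totals without the genes that rose, were chosen after seeing the data, and the other alternatives were set beforehand. Ifng stayed past the test under each alternative in which its fold change was estimated, with log2 fold changes of 7.01 to 7.77. No result changed direction past its threshold; where neither fit passed, a change of sign was not counted. Among counts, 124 of the alternatives lay within 1.5 times the reported value and 6 did not. Genes lower fell to 458 when tested against a fold change of 1.2, a stricter test by construction, and to 752 on totals without the genes that rose. Genes lower by 2-fold or more rose to 179 with no filter on low counts and to 183 in DESeq2; the cause was not tested. Lists higher rose to 21 with fry, which does not compare a list with other genes, and lists lower dropped to 0 with an estimated correlation. Leaving out each library in turn gave 1924 to 2332 genes higher, 1047 to 1699 lower, 953 to 1115 higher and 108 to 142 lower by 2-fold or more, 12 to 14 lists higher and 4 to 7 lists lower. Of the genes named by rule, 1916 comparisons with an alternative kept their side of the threshold and 13, for Psmb5, Psmb7, Jak1, Srxn1, Nptxr and Syt1, newly passed. Of single lists, 745 comparisons kept their side, 29 newly passed and 17 were lost. The GABAergic list (adjusted p = 0.0394) was lost without Control 1, Control 2, Control 3, IFNG 5 or IFNG 6 (0.0709, 0.0561, 0.0505, 0.0989 and 0.0589) and without IFNG 3 and IFNG 5 together (0.0637). The channel list (0.0312) was lost without Control 3 (0.0633), without IFNG 5 (0.104), without IFNG 3 and IFNG 5 (0.136) and with fry (0.0519). The remaining losses, those of all 6 lower lists and of NRF2 targets, came with the estimated correlation. Without IFNG 2, 2942 of the 3676 calls remained, the fewest of any library left out. Oas3 had no value without IFNG 5 or IFNG 6 and under the 1 CPM filter, and nor did the endothelial list under that filter. Replicate numbers are shared between the groups, but same-numbered libraries correlated at -0.00096 to 0.124 in their deviations from the group means, not all over 0.1, so the numbers are not taken as pairs; 2 of the 6 Control libraries correlated best with their own number. With the replicate number as a block, 2114 genes were higher and 1563 lower, and 3436 of the 3676 calls remained. Depth limits the genes with few Control counts, whose folds are bounds or carry wide intervals.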

Other observations

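The tests of interneuron genes in this part were chosen after the result was seen, except the criterion on markers not yet looked at, which was set beforehand. The genes in the next 2 paragraphs, and the correlations with Ifng, were picked after their values were seen.

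In the list of glutathione and ferroptosis genes Ptgs2, the inducible cyclooxygenase gene, fell from 10.9 ± 6.83 to 0.622 ± 0.420 CPM (SD, n = 6 each; edgeR log2 fold change -4.20 ± 0.45, adjusted p = 4.95e-07). Steap3, an iron reductase gene, rose by 3.96 ± 0.31, Gpx1, a glutathione peroxidase gene, by 1.86 ± 0.13, and the cystine transporter gene Slc7a11 by 1.38 ± 0.24, while the transferrin receptor gene Tfrc fell by 0.45. Gpx4, which protects membranes from lipid peroxidation, stood at 0.20 ± 0.12 (adjusted p = 0.253). The small heat shock gene Hspb8 rose by 2.98 ± 0.17 and its partner Bag3 by 1.91 ± 0.24, while Hspa1b fell by 0.59.

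Among lysosomal genes, Lamp2 rose by 1.66 ± 0.14, Lamp1 by 0.89 ± 0.11 and the protease gene Ctsb by 0.90 ± 0.13. Of genes that help proteins fold in the endoplasmic reticulum, Creld2, Pdia4 and Calr rose by 0.90, 0.80 and 0.53, while Hyou1, Pdia6, Sdf2l1 and Dnajb9 did not pass (adjusted p = 0.115, 0.327, 0.257 and 0.669). Trib3 and Ppp1r15a, targets of the integrated stress response, fell by 1.56 and 0.66, while Ddit3, Atf3, Sesn2, Asns, Chac1 and Atf4, of the same response, did not pass (adjusted p = 0.864, 0.964, 0.648, 0.113, 0.102 and 0.126). Among genes of apoptosis, the inhibitor gene Bcl2 rose by 1.11 ± 0.13.

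Several genes of interneurons that arise in the caudal ganglionic eminence fell. Vip, Calb2, Sp8, Adarb2 and Synpr, picked because they fell, had log2 fold changes of -1.85 to -1.19, while Sst and Sox6, of interneurons from the medial eminence, rose by 0.77 and 1.05. The criterion set beforehand for fewer GABAergic neurons of every kind was a difference within 0.3 between medians of caudal markers not yet looked at and medial markers; it was met, at -0.09064 (exact permutation p = 0.143, 8 markers each), but it would be met equally if neither class had fallen, and the medians were -0.15 and -0.06. A second test, chosen after that result, asked whether 11 medial and shared markers, none picked for a fall, lay near the 5 genes. Their median was -0.09871 (exact 98.83% interval -0.3245 to 0.7688), so as a set they did not fall by as much. Unpicked markers tend to lie above genes picked for their fall, and the 8 unpicked caudal markers also had a median of only -0.15. The second test therefore does not decide on an equal loss of every kind. Fewer interneurons of the caudal type is not decided either by the difference of -0.09064, because Htr3a and Npas1 fell by 1.21 and 0.94 while Cxcl14 rose by 0.75.

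Across the 6 IFNG libraries, Ifng was compared with 10 measures (exact permutation, 720 arrangements, Benjamini-Hochberg adjusted). By Pearson's r 6 list scores passed, and by Spearman's rho 1 passed, that of presynaptic genes. The presynaptic scores of IFNG 1, IFNG 6 and IFNG 4 were nearly tied, at 8.4144, 8.414 and 8.4133 mean log2 CPM. Ifng was also close in IFNG 4 and IFNG 2, at 12.2 and 12.57 CPM. The rho of presynaptic genes therefore rests on small differences and does not establish a strict order. For type I signature genes Pearson's r was 0.94 (p = 0.00833, adjusted p = 0.0333; Spearman's rho 0.77, p = 0.103, adjusted p = 0.147) and 0.90 without the 2 libraries farthest from the median of Ifng. For interferon-gamma response genes r was 0.88 (p = 0.0236, adjusted p = 0.0394; rho 0.60, p = 0.242, adjusted p = 0.269) and 0.90 without those 2. For class I presentation r was 0.91 (p = 0.0139, adjusted p = 0.0333; rho 0.83, p = 0.0583, adjusted p = 0.0972) and 0.65 without them, and for class II presentation 0.90 (p = 0.0167, adjusted p = 0.0333; rho 0.83, p = 0.0583, adjusted p = 0.0972) and 0.64. For astrocyte markers r was 0.90 (p = 0.0125, adjusted p = 0.0333; rho 0.83, p = 0.0583, adjusted p = 0.0972) and 0.64 without those 2. For pan-neuronal genes r was -0.89 (p = 0.0153, adjusted p = 0.0333; rho -0.83, p = 0.0583, adjusted p = 0.0972) and -0.48 without them, so the relations of these last 4 lists rest in part on 2 libraries. Presynaptic genes passed by rho alone (rho -1, p = 0.00278, adjusted p = 0.0278; r -0.80, p = 0.0431, adjusted p = 0.0590; r -0.51 without them). The immunoproteasome list did not pass (r 0.79, p = 0.0639, adjusted p = 0.0710; rho 0.83, p = 0.0583, adjusted p = 0.0972; r 0.45 without them), nor did activity-regulated genes (r -0.82, p = 0.0472, adjusted p = 0.0590; rho -0.60, p = 0.242, adjusted p = 0.269; r -0.47 without them). For library totals r was 0.41 (p = 0.429, adjusted p = 0.429; rho 0.54, p = 0.297, adjusted p = 0.297) and 0.52 without them.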
